A study of Mus musculus with 6 samples.

How the data were processed

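Both kidneys of 3 CD-1 mice were measured on 6 single-colour Agilent mouse expression arrays (design 014868), 1 array per kidney. CD-1 is an outbred stock, so the mice are not genetically identical. The labels name each mouse by a number (495, 485 and 512) and say which kidney lay behind the tied left ureter and which was the untied right kidney. They call the material kidney in the tissue field and primary cells in the cell type and growth fields, and nothing in the sources used here settles which was extracted. The time between ligation and sampling is not given in the sources used here. Each group holds 1 kidney from each of the same 3 animals. In the paired fit, p-values of single genes measure the spread of the differences within these animals, moderated across genes. The camera p-values of gene lists given below compare genes with genes and do not measure the spread between animals. The number of arrays limits the precision.

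Total RNA was labelled with Cy3 as fragmented cRNA, per the labels' protocols. The authors deposited 1 scanner table per array, whose processed signal is a linear intensity that Agilent Feature Extraction had background-subtracted and detrended within the array, per the file headers, with no scaling between arrays. The headers give Feature Extraction version 10.5.1.1, while the submitters' processing notes name version 9.1, and the difference was not resolved. Spot means and local background medians are raw intensities, per the file headers. The flags for spots well above background, saturated or outlying are values of 0 or 1. The authors also deposited a value table for the series, which holds a linear ratio: each value equalled the processed signal divided by the array's median (a factor between 62.8 and 176, with 99% of spots within 0.00289% of it), so every column has a median of 1.00 and its rows are the spot numbers of the scanner tables. Probe positions are those of the mm8 genome build that the headers name.

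Control spots were left out, which left 43379 spots per array, and spots flagged as outliers (between 43 and 79 per array) were removed. The processed signal was log2-transformed, the array's 75th percentile was subtracted, and spots of one probe were averaged. No spot was saturated (0 on each array). Of 41174 probes, 24 with a flagged array were left out, 24375 took their current symbol through a RefSeq accession, and 16799 kept the name in the file, of which 6301 were current symbols. The symbols came from a RefSeq gene table of another genome build, which was used for names alone. A probe counted as above background where at least 0.5 of its spots were well above background. Probes above background on all 3 arrays of at least 1 group were kept, and the probe with the highest mean stood for its gene, which gave 19598 genes, 14640 of them under a current symbol. Of the 112 genes named by the rule below, 42 had several probes, and those of Havcr1 and Synpo differed in sign.

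Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the mouse as a fixed block and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and a second count asked for an absolute log2 fold change of at least 1. The block leaves 2 residual degrees of freedom, to which eBayes added 2.06. Log2 fold changes are ligated minus contralateral and are given ± SE. The pairing comes from the mouse numbers in the labels. Deviations from the group means correlated across genes between the kidneys of one mouse (r = 0.194 in mouse 495, 0.481 in mouse 485 and 0.271 in mouse 512), and every such r exceeded those between kidneys of different mice. Slide is nested in the mouse, because slide 1 held both kidneys of mice 495 and 485 and slide 2 those of mouse 512.

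Where a probe was below background on some or all arrays of the dimmer group and this changes the fold, the fold is a lower bound, written "at least", while log2 values stay as fitted: the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among probes above background.

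Chosen before the data were examined were the tests, the settings to be varied, 33 gene lists and the rule for naming genes. The rule took, from called genes that changed the same way in all 3 mice and carry a plain symbol, the 10 largest rises and the 10 largest falls. It added from each list the 3 called members with the largest change (or, with none called, the member with the smallest p), and Col1a1, Fn1, Acta2, Tgfb1, Havcr1, Lcn2, Umod and Slc34a1 in any case. Other genes named were chosen after their values were seen. Lists were tested with camera at its preset inter-gene correlation of 0.01, which compares a list with all other genes. Beside it stood camera with an estimated correlation and fry, which asks whether the members move, on balance, one way. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so hardly any list could pass it here. Not passing it therefore does not show that a list stayed level. Its adjusted p of 0.44 was shared by lists with unadjusted p from 0.0388 to 0.333. Lists of at least 4 tested members entered, which were all 33. Many list members, marker genes included, are expressed by more than 1 kidney cell type, and Fbp1, Ppargc1a and Slc4a1 each stand in more than 1 list.

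The scripts were tested on simulated data with the same 19598 genes. With 200 genes changed, 4% were recovered at a log2 change of 1, 86% at 2 and 100% at 3 and at 4, and 7 of 152 calls were false. With 8000 genes changed, recovery was 86.7%, 98%, 99.6% and 99.9% at these sizes, and 230 of 7914 calls were false. In a simulation of lists, both shifted lists were called and 0 others. The simulated noise was independent between genes, whereas the correlations estimated within the real lists reached 0.99. This simulation therefore cannot show how often camera calls lists of correlated members that do not shift. Nor can the simulations of genes show recovery or false calls where 1 kidney deviates in many genes together, as in mouse 512.

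The settings varied were quantile normalization, centring on the median, normexp background correction (offset 50) of the spot means, no filter on dim probes, a filter on all 6 arrays, no mouse block, the slide as the block, the mean of a gene's probes, an intensity trend in eBayes, the deposited value table, and leaving out each mouse in turn. Added after seeing the data were an unpaired fit without the contralateral kidney of mouse 512 and centring on 8 of the 10 spike-in control probes, those above background on all arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.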

Results

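The data compare the left kidney behind a tied ureter with the untied right kidney of the same animal in 3 CD-1 mice (495, 485 and 512). Unilateral ureteral obstruction is a model of renal fibrosis, and the series text calls the right kidney the internal control; the comparison asks which genes change in the obstructed kidney. The 75th percentile of the processed signal was 740, 671 and 1106 in the contralateral kidneys of mice 495, 485 and 512, and 1362, 1432 and 1068 in their ligated kidneys. Between 65.3% and 69.0% of probes were well above background on the contralateral arrays, against 71.6% to 74.2% on the ligated ones. The median spot stood 2.70 to 4.99 times over its local background in contralateral kidneys and 5.54 to 6.35 times in ligated kidneys.

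Genes of the extracellular matrix and of macrophages and lymphocytes were higher in the ligated kidney, and genes of tubular transport and mitochondrial metabolism were lower. These are shifts of list medians. With a correlation estimated within each list, 0 of 33 lists passed camera (smallest adjusted p 0.44). At 2 residual degrees of freedom that test had little power, so it settles neither a shift nor its absence. The medians of the T and NK cell and the B and plasma cell lists were 2.51 and 1.62, and 0.87 and 0.86 with normexp. Retnla, a secreted protein of alternatively activated macrophages, rose 103-fold (log2 fold change 6.68 ± 0.57, n = 3 mice), and Slc22a8, an organic anion transporter of the proximal tubule, fell 17.1-fold (-4.10 ± 0.93). Of 19598 genes tested, 6019 passed the threshold, 3135 of them higher and 2884 lower. At least a 2-fold change was seen for 4320 of these, 2562 higher and 1758 lower. Each of the 6019 genes changed in the same direction in all 3 mice. With 3 pairs no gene could pass this threshold otherwise, so this agreement is no separate evidence. The same direction in all 3 mice was seen for 72.2% of all genes, called or not, where chance gives 25%. The smallest adjusted p was 0.0221. The probes of 365 genes that rose were above background on no contralateral array, and those of 11 genes that fell were above background on no ligated array.

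These counts depend on which mice are in the fit. Without mouse 495 or without mouse 485, 0 genes passed in limma (4979 and 5019 at an unadjusted p under 0.05, against 9833 with all mice). The 0 members of lists and families given below for these 2 fits follow from this and say nothing particular about a list. Camera at its preset correlation passed 26 of 33 lists in each of them. Without mouse 512 the count of genes was 11122, or 7271 at least 2-fold. The contralateral kidney of mouse 512 was added to the doubted arrays after the data were seen: an unpaired fit without it called 11185 genes. With the slide in place of the mouse as the block, 7573 genes passed; slide 1 alone is the fit without mouse 512, and slide 2 holds a single pair. The balance of rises and falls moved with the scaling, the background correction and the filter. Against the 3135 higher and 2884 lower calls, there were 2561 higher and 5938 lower with centring on the median and 2449 and 653 with centring on the spike-in spots. With normexp background correction there were 1992 and 2787, and with no filter on dim probes, which tests 28468 genes, 1760 and 902. The median log2 change of all genes was -0.01. It became -0.32 with centring on the median and 0.31 with centring on the spike-in spots, so that changes are relative to that shift. It was -0.18 with normexp, which also shrinks changes of dim probes. With no filter it was -0.23, where dim genes were added under the same scaling, and Fn1 stayed at 2.70.

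Among the 10 largest rises, Spink12, a Kazal-type protease inhibitor, was 54.6-fold higher (5.77 ± 1.05) and Iqsec3, a guanine nucleotide exchange factor, at least 24.8-fold (5.22 ± 1.1). Cxcl5, a neutrophil-attracting chemokine, rose at least 14.8-fold (4.92 ± 0.75), and the macrophage elastase Mmp12 rose at least 11.5-fold (4.89 ± 0.56); the probes of Iqsec3, Cxcl5 and Mmp12 were above background on 1 contralateral array. The eosinophil-associated ribonucleases Ear1 (29.9-fold), Ear6 (at least 20.6-fold) and Ear10 (at least 23.8-fold) rose too; they are near-identical relatives, so their probes may share signal and the members cannot be separated with certainty. Wfdc18 rose 27.0-fold and Plekhs1 at least 9.26-fold, the latter above background on 1 contralateral array and with a second probe at a log2 change of 2.19. The largest falls after Slc22a8 were those of the angiotensin-(1-7) receptor gene Mas1 (12.3-fold), the anion transporter gene Slc22a6 (12.1-fold) and Cyp4a14 (11.9-fold), a fatty acid hydroxylase gene. Apom, an apolipoprotein made in the proximal tubule, fell 11.1-fold, the carboxylesterase gene Ces2f 10.8-fold, the coagulation factor gene F13b 9.98-fold, Cyp4a12a 9.48-fold and Perm1, a regulator of mitochondrial genes, at least 8.94-fold. The NADPH oxidase gene Duox1 fell by 3.46 on the log2 scale (± 0.68). Cyp4a and Ces2 genes also belong to families of similar sequence. In mm8, the probe of Retnla lies on chromosome 16 from 48763960 to 48764019, that of Ear1 on chromosome 14 from 42698911 to 42698970, and that of Slc22a8 on chromosome 19 from 8677317 to 8677376. Mouse 512 had the smallest change of the 3 mice for each of these 10 rises except Retnla, among them Spink12 (2.86 against 6.71 and 7.74), and for Retnla the largest (8.13 against 5.42 and 6.50).

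**Figure D1:**
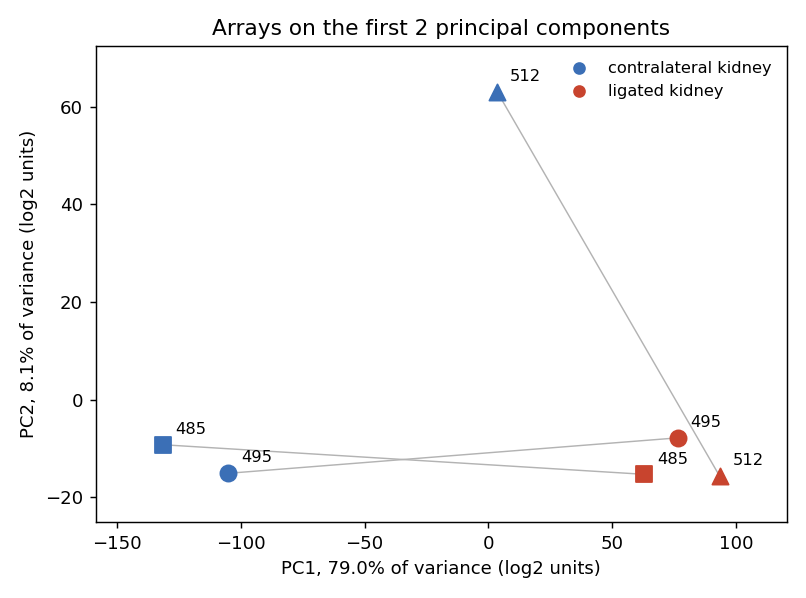
Positions of the 6 arrays on the first 2 principal components of 19598 genes, with PC1 (79.0% of the variance) on the x axis and PC2 (8.1%) on the y axis, both in log2 units; blue points are contralateral and red points ligated kidneys, and grey lines join the kidneys of one mouse. Ligated kidneys lie between 63.0 and 93.4 on PC1, the contralateral kidneys of mice 485 and 495 at -131.6 and -105.0, and that of mouse 512 at 3.6.

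Matrix genes rose. Of 16 collagen genes, 15 rose and 0 fell (16 rose adjusted over the list alone), with a median log2 fold change of 2.71 (camera adjusted p = 3.66e-06, and adjusted p = 0.44 with an estimated correlation). Col5a2 rose 17.7-fold (4.15 ± 0.70), Col12a1 17.4-fold (4.12 ± 0.70) and Col1a1, a chain of type I collagen, 14.5-fold (3.86 ± 0.91, adjusted p = 0.0463). Col1a1 was not called without the mouse block (0.0549), with no filter (0.0633) or with the mean of its probes (0.0519), and its other probes, at 3.55 and 3.32, did not pass (0.0562 and 0.0512). The Col1a1 probe lies on chromosome 11 from 94767851 to 94767910 in mm8. Matrix glycoproteins, proteoglycans and cross-linkers had 16 of 20 members higher and 0 lower (19 higher adjusted over the list alone), at a median of 2.47 (camera adjusted p = 8.44e-08, and adjusted p = 0.44 with an estimated correlation). The collagen cross-linking enzyme Lox rose at least 11.6-fold, tenascin C (Tnc) at least 10.45-fold and versican (Vcan) at least 4.14-fold, each above background on 1 contralateral array; with normexp the Vcan value was 0.57 and no longer past the threshold. Of 17 matrix proteases and their inhibitors, 12 rose, among them Mmp12, Mmp7 (22.6-fold) and Mmp3 (at least 16.2-fold), and 1 fell (14 and 1 adjusted over the list alone), at a median of 3.15. Their camera adjusted p was 3.46e-05, and adjusted p = 0.44 with an estimated correlation. With normexp their median was 1.81. The one that fell was the metalloprotease inhibitor Timp3 (-1.32 ± 0.20), picked out after its value was seen; on the spike-in scale 0 fell.

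Stromal and signalling genes followed. Of 12 myofibroblast and pericyte markers, 10 rose and 0 fell (10 and 0 adjusted over the list alone), at a median of 2.10 (camera adjusted p = 3.04e-05, and adjusted p = 0.44 with an estimated correlation). Thy1 rose 10.6-fold (3.41 ± 0.33), the PDGF receptor gene Pdgfra 7.12-fold (2.83 ± 0.27), and the probe of Fap, a fibroblast surface protease, at least 7.05-fold, while a second Fap probe rose by 1.57 on the log2 scale. Of 17 genes of TGF-beta signalling, 8 rose and 1 fell (8 and 1 adjusted over the list alone), at a median of 0.74 (camera adjusted p = 0.00293, and adjusted p = 0.44 with an estimated correlation). The latent TGF-beta binding protein gene Ltbp2 rose 18.2-fold, the activin subunit gene Inhba 10.3-fold and Tgfb1 4.62-fold, while Bmp7, a BMP ligand picked out after its value was seen, fell (-1.68 ± 0.28). Wnt signalling had 7 of 18 members higher and 0 lower (9 and 0 adjusted over the list alone), at a median of 0.95 (camera adjusted p = 0.00486, and adjusted p = 0.44 with an estimated correlation). Axin2, a target gene of the pathway, rose at least 6.31-fold, Wnt4 at least 5.92-fold and Lef1 at least 4.07-fold, the last at 0.48 and not called with normexp, where the list median was also 0.48 and 5 members rose. Of 12 epithelial-mesenchymal transition regulators and cadherins, 7 rose and 1 fell (9 and 1 adjusted over the list alone), at a median of 1.38. Their camera adjusted p was 0.0027, and adjusted p = 0.44 with an estimated correlation; with normexp the median was 0.63 and 4 rose. Snai1 rose 5.64-fold, Snai2 5.12-fold and the probe of Twist2 at least 6.45-fold (0.83 and not called with normexp), and the kidney cadherin gene Cdh16, picked out after its value was seen, fell (-0.95 ± 0.20).

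Matrix and stromal lists had their smallest median differences within pairs in mouse 512, whose contralateral kidney lay toward the ligated ones. Against the other 2 contralateral kidneys, the median difference of collagen genes was 2.11 in that kidney. It was 3.48 in the ligated kidney of mouse 512 and 3.41 in the other ligated kidneys. The medians in mice 495, 485 and 512 were 3.17, 3.58 and 1.41 for collagen genes, 2.38, 3.06 and 1.86 for matrix glycoproteins, 3.14, 3.50 and 1.85 for proteases, and 2.24, 2.69 and 1.12 for myofibroblast and pericyte markers. They were 0.77, 1.02 and 0.28 for TGF-beta signalling, 1.00, 0.90 and 0.89 for Wnt signalling, and 1.58, 1.59 and 0.87 for the transition regulators. In the contralateral kidney of mouse 512, 15 of 16 collagen genes stood above both other contralateral kidneys, as did 9 of 18 Wnt genes, while 7 Wnt genes stood below both. With mouse 495 or mouse 485 left out, 0 members of these 7 lists passed, while the collagen median was 2.51 and 2.33 and that of matrix glycoproteins 2.47 and 2.28. Without mouse 512, the members that rose numbered 16, 18, 14, 10, 11, 10 and 9 in the order given, and 3 Wnt and 2 TGF-beta members fell, as did 1 member each of the protease and the transition lists. With no filter the counts of rises were 7, 13, 9, 7, 6, 6 and 6.

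**Figure D2:**
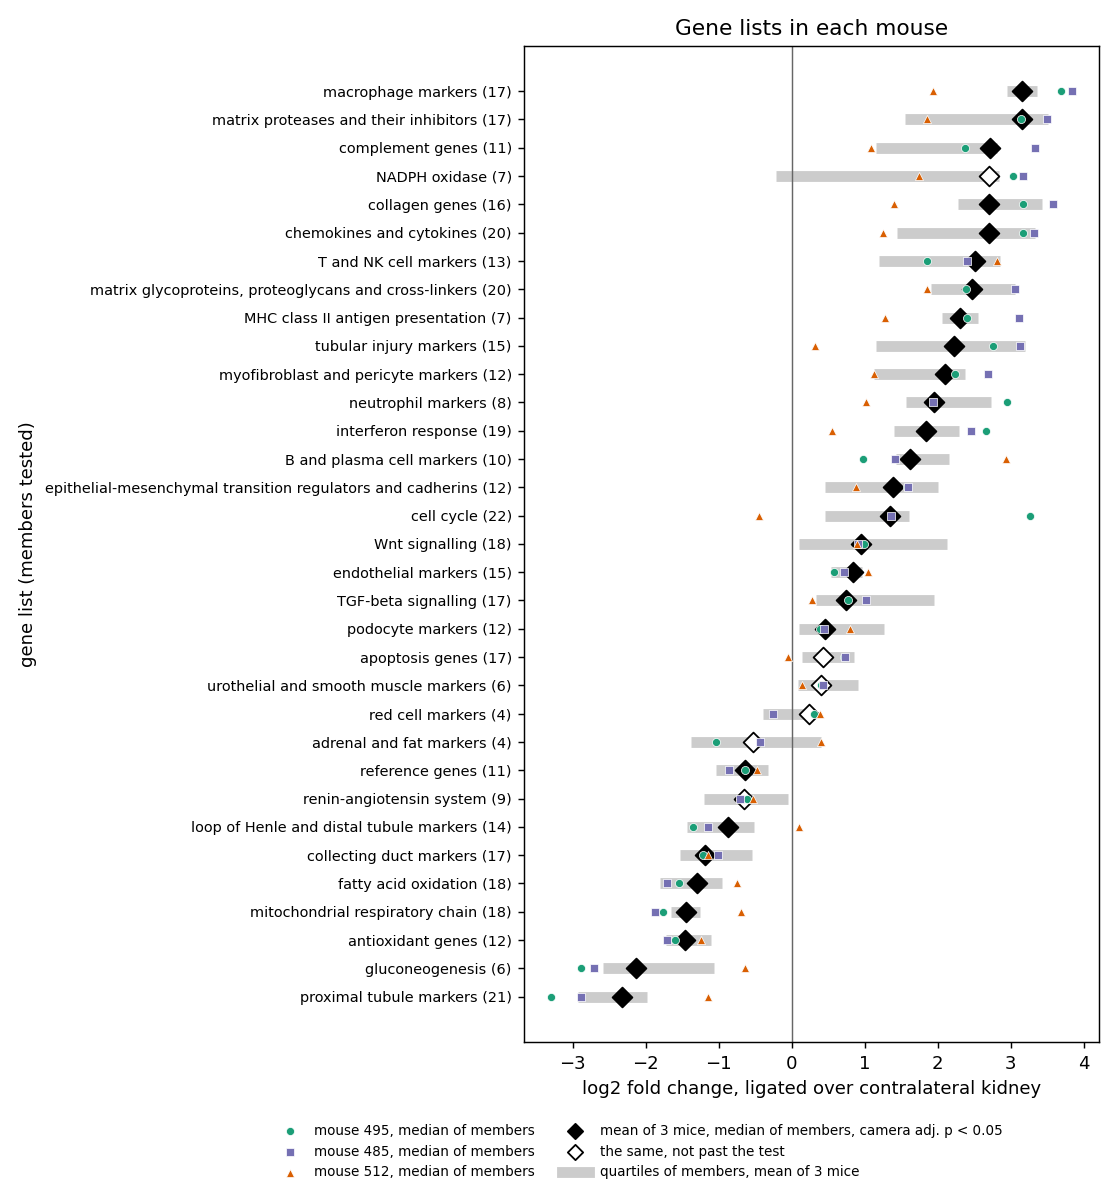
Median log2 fold change (ligated over contralateral, x axis) of the tested members of 33 gene lists (y axis), per mouse as coloured points and for the mean of 3 mice as diamonds, filled where camera passed at its preset correlation; grey bars span the quartiles of the members. Macrophage markers and matrix proteases lie highest (both 3.15) and proximal tubule markers lowest (-2.33); mouse 512 lies nearer to 0 than the other mice in each (1.94, 1.85 and -1.15).

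Tubule transport genes fell in the ligated kidney. Of 21 proximal tubule markers, 13 fell and 0 rose (20 fell adjusted over the list alone), at a median of -2.33 (camera adjusted p = 2.46e-06, and adjusted p = 0.44 with an estimated correlation). Slc22a8 and Slc22a6 led the list, followed by the dicarboxylate transporter gene Slc13a3, 8.77-fold lower. Of 17 collecting duct markers, 8 fell and 0 rose (11 fell adjusted over the list alone), at a median of -1.18 (camera adjusted p = 5.74e-05, and adjusted p = 0.44 with an estimated correlation). The water channel genes Aqp2 and Aqp3 fell 7.35-fold (-2.88 ± 0.15) and 6.32-fold (-2.66 ± 0.35), and Slc26a4, the chloride exchanger pendrin of intercalated cells, 5.82-fold. The loop of Henle and distal tubule list had 2 of 14 members lower and 0 higher (0 adjusted over the list alone), at a median of -0.88 (camera adjusted p = 0.0269, and adjusted p = 0.57 with an estimated correlation). That list was not called with quantile normalization (0.0578), centring on the median (0.0656), normexp (0.0574), the filter on all 6 arrays (0.0606) or the deposited value table (0.0657). Those 2 were Slc12a3, the thiazide-sensitive sodium chloride transporter (3.57-fold), and the claudin gene Cldn10 (2.55-fold). In mice 495, 485 and 512 the list medians were -3.30, -2.89 and -1.15 for the proximal tubule and -1.21, -1.01 and -1.15 for the collecting duct. They were -1.35, -1.15 and 0.11 for the loop and distal tubule. Against the other 2 contralateral kidneys, proximal tubule markers lay at -2.03 in the contralateral kidney of mouse 512. They lay at -3.27 in its ligated kidney and -2.97 in the other ligated kidneys. For the loop and distal tubule list these were -1.14, -0.96 and -1.30. Leaving out mouse 495 or mouse 485 left 0 members past the threshold; without mouse 512, 20, 12 and 13 fell, and 1 of the loop and distal tubule list rose. With no filter 7, 6 and 0 fell. The falls numbered 20, 12 and 6 with centring on the median and 16, 4 and 2 on the spike-in scale.

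Among the 33 lists, the medians of tubular injury and cell cycle genes differed most between the mice. Of 15 tubular injury markers, 3 rose and 0 fell (8 rose adjusted over the list alone), at a median of 2.23 (camera adjusted p = 0.00181, and adjusted p = 0.52 with an estimated correlation). They were the hyaluronan receptor gene Cd44 (17.3-fold), the adhesion molecule gene Vcam1 (13.9-fold) and Sox4 (4.68-fold). Their median was 2.76 in mouse 495, 3.12 in mouse 485 and 0.32 in mouse 512. None of the 22 cell cycle genes passed (0 higher and 0 lower over all genes, and 0 adjusted over the list alone), although the list as a whole did, with a median of 1.34 (camera adjusted p = 0.0274, and adjusted p = 0.64 with an estimated correlation). Aurkb, a mitotic kinase gene and the member with the smallest p, stood at 2.20 ± 0.87 (adjusted p = 0.117). The cell cycle median was 3.27 in mouse 495, 1.36 in mouse 485 and -0.45 in mouse 512, and the list lost its call without mouse 495 (camera adjusted p = 0.237) or without mouse 485 (0.0842); with normexp its median was 0.66. With no filter 1 injury marker rose, against 9 on the spike-in scale, 7 with the slide as the block and 6 with normexp or an intensity trend. Without mouse 512, 14 injury markers and 16 cell cycle genes rose, while without mouse 495 or mouse 485 0 did. Of 17 apoptosis genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), and the list did not pass (median 0.43, camera adjusted p = 0.128), although it did without mouse 512 (camera adjusted p = 0.0106), when 11 members rose, and with quantile normalization (0.0430), normexp (0.0153), no filter (0.0220) and the filter on all 6 arrays (0.0476). The risers were Bcl2l11, a promoter of apoptosis (2.59-fold, with other probes at log2 changes of 0.72 and 0.32 that did not pass), and the inflammasome adaptor gene Pycard (2.36-fold), and Bid fell 1.93-fold.

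Energy metabolism genes fell together. Of 18 genes of the mitochondrial respiratory chain, 17 fell and 0 rose (18 fell adjusted over the list alone), at a median of -1.45 (camera adjusted p = 3.66e-06, and adjusted p = 0.44 with an estimated correlation). Cytochrome c (Cycs) fell 3.29-fold (-1.72 ± 0.26), the complex II subunit gene Sdhb 3.29-fold and the complex III subunit gene Cyc1 3.28-fold. Fatty acid oxidation had 14 of 18 members lower and 0 higher (17 lower and 1 higher adjusted over the list alone), at a median of -1.30 (camera adjusted p = 1.34e-05, and adjusted p = 0.44 with an estimated correlation). The peroxisomal enzyme gene Ehhadh fell 6.22-fold, and Ppara, a nuclear receptor that drives such genes, 4.47-fold. Of 6 gluconeogenesis genes, 3 fell and 0 rose (5 fell adjusted over the list alone): Pcx (6.34-fold), Fbp1 (5.02-fold) and the coactivator gene Ppargc1a (1.71-fold). Their median was -2.13 (camera adjusted p = 0.0383, and adjusted p = 0.44 with an estimated correlation). Gluconeogenesis was not called with quantile normalization (0.0644), centring on the median (0.0998), normexp (0.0580), no filter (0.0524), the filter on all 6 arrays (0.0649) or the deposited value table (0.100). Antioxidant genes had 11 of 12 members lower and 0 higher (11 adjusted over the list alone), at a median of -1.46 (camera adjusted p = 1.34e-05, and adjusted p = 0.44 with an estimated correlation). The quinone reductase gene Nqo1 fell 4.85-fold (-2.28 ± 0.15), catalase (Cat) 3.97-fold and the extracellular superoxide dismutase gene Sod3 3.91-fold. Medians in mice 495, 485 and 512 were -1.76, -1.87 and -0.69 for the respiratory chain and -1.55, -1.70 and -0.75 for fatty acid oxidation. They were -2.89, -2.70 and -0.64 for gluconeogenesis, and -1.60, -1.71 and -1.24 for antioxidant genes. Against the other 2 contralateral kidneys, respiratory chain genes lay at -1.21 in the contralateral kidney of mouse 512. They lay at -1.90 in its ligated kidney and -1.83 in the other ligated kidneys. On the spike-in scale, the members that fell numbered 5, 5, 4 and 3 in these lists, and 1 fatty acid oxidation gene rose. With no filter on dim probes they numbered 1, 5, 1 and 8. With mouse 495 or mouse 485 left out they numbered 0, and with mouse 512 left out 18, 17, 5 and 11.

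Common reference genes were not level. Of 11, 5 fell and 0 rose (5 adjusted over the list alone), at a median of -0.64 (camera adjusted p = 0.00831, and adjusted p = 0.44 with an estimated correlation). The glycolytic enzyme genes Pgk1 and Gapdh fell 2.60-fold and 2.52-fold, and Ppia, picked out after its value was seen, fell too (-0.64 ± 0.14). The list kept a negative median under every scaling tried but was not called with quantile normalization (camera adjusted p = 0.325), on the spike-in scale 0 of its members passed, and with no filter 1 did. It fell in each mouse, with medians of -0.64, -0.85 and -0.47 in mice 495, 485 and 512. Of 9 genes of the renin-angiotensin system, 1 rose and 3 fell (1 and 6 adjusted over the list alone), and the list did not pass (median -0.65, camera adjusted p = 0.102), except on the spike-in scale (0.0468). Mas1 fell most, the angiotensin-converting enzyme gene Ace fell 4.11-fold and the aminopeptidase gene Enpep 2.31-fold, whereas the renin gene Ren1, picked out after its value was seen, rose (1.20 ± 0.14). NADPH oxidase genes had 4 of 7 members higher and 1 lower (4 and 2 adjusted over the list alone), at a median of 2.71 that did not pass (camera adjusted p = 0.157, and fry adjusted p = 0.0216). It passed camera with centring on the median (0.0440), normexp (0.0208), no filter (0.0419) and the deposited value table (0.0440). The phagocyte oxidase genes Ncf1 (11.4-fold), Cybb (7.52-fold) and Rac2 (6.81-fold) rose. Of genes picked out after their values were seen, Ncf4 rose (2.71 ± 0.37) and the renal oxidase gene Nox4 fell (-1.75 ± 0.29). Without mouse 495 or mouse 485, 0 members of these lists passed, and without mouse 512, 6 reference genes and 6 of 10 renin-angiotensin genes fell.

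Markers of macrophages rose most among the cell type lists. Of 17 macrophage markers, 16 rose and 0 fell (16 adjusted over the list alone), at a median of 3.15 (camera adjusted p = 3.09e-07, and adjusted p = 0.44 with an estimated correlation). Ms4a7 rose 13.6-fold (3.76 ± 0.30), the mannose receptor gene Mrc1 12.2-fold and Adgre1, which encodes a macrophage surface receptor, 10.7-fold. T and NK cell markers had 8 of 13 members higher and 1 lower (10 and 1 adjusted over the list alone), at a median of 2.51 (camera adjusted p = 7.76e-05, and adjusted p = 0.44 with an estimated correlation). Cd3d and Cd3g, parts of the T cell receptor complex, rose 8.92-fold (3.16 ± 0.19) and 8.51-fold, and Il2rb 7.33-fold, while Cd8b1, picked out after its value was seen, fell (-1.59 ± 0.33), and with no filter, the mean of the probes or the spike-in scale 0 members fell. Of 10 B and plasma cell markers, 6 rose and 0 fell (8 adjusted over the list alone), at a median of 1.62 (camera adjusted p = 0.000664, and adjusted p = 0.44 with an estimated correlation). Cd22 rose at least 6.47-fold, although with normexp its value was 0.99 and not past the threshold, the B cell receptor subunit gene Cd79b 4.83-fold and Pou2af1 3.52-fold. Of 8 neutrophil markers, 4 rose and 0 fell (7 adjusted over the list alone), at a median of 1.95, or 1.88 with the Mmp8 probe at its bound (camera adjusted p = 0.00301, and adjusted p = 0.44 with an estimated correlation). Lactoferrin (Ltf) rose at least 4.71-fold, the growth factor receptor gene Csf3r 6.51-fold, the probe of the collagenase gene Mmp8 at least 3.07-fold, and S100a8, named after its value was seen, 1.99 ± 0.42 on the log2 scale; with normexp Ltf and Mmp8 were at 0.73 and 0.13 and not called. With normexp the list medians were 3.01 for macrophages but 0.87 for T and NK cells (6 higher), 0.86 for B and plasma cells (4 higher) and 0.60 for neutrophils (3 higher). Medians in mice 495, 485 and 512 were 3.69, 3.85 and 1.94 for macrophages, but 1.86, 2.40 and 2.81 for T and NK cells. They were 0.97, 1.42 and 2.94 for B and plasma cells, and 2.95, 1.94 and 1.02 for neutrophils. Against the other 2 contralateral kidneys, macrophage markers lay 3.98 higher in the ligated kidney of mouse 512 and 3.81 higher in the other ligated kidneys. Neutrophil markers lay 0.53 and 2.44 higher. Without mouse 495 or mouse 485, 0 members passed, and without mouse 512, 17, 9, 8 and 6 rose. With no filter 14, 8, 3 and 2 rose.

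Inflammatory mediators rose with them. Of 20 chemokines and cytokines, 11 rose and 0 fell (13 adjusted over the list alone), at a median of 2.70 (camera adjusted p = 2.91e-05, and adjusted p = 0.44 with an estimated correlation). The monocyte attractants Ccl8 and Ccl7 rose 19.1-fold and 16.4-fold and the interferon-induced chemokine gene Cxcl9 at least 10.2-fold; the list median was 1.43 with normexp. Of 11 complement genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), at a median of 2.71 (camera adjusted p = 0.0137, and adjusted p = 0.52 with an estimated correlation). The receptor gene C3ar1 rose at least 11.03-fold, and the C1 inhibitor gene Serping1 rose 7.16-fold and the properdin gene Cfp 7.15-fold, while C4b (-1.11 ± 0.23) and Cfb (-0.71 ± 0.15), picked out after their values were seen, fell. In this list 0 members fell without the mouse block, with the slide as the block, with quantile normalization, with no filter, on the spike-in scale or in the unpaired fit without the contralateral kidney of mouse 512. Interferon response genes had 10 of 19 members higher and 0 lower (18 adjusted over the list alone), at a median of 1.84 (camera adjusted p = 6.16e-06, and adjusted p = 0.44 with an estimated correlation). Gbp2 rose 8.18-fold, the immunoproteasome subunit gene Psmb8 6.17-fold and Oasl2 6.13-fold. MHC class II antigen presentation had 6 of 7 members higher and 0 lower (7 adjusted over the list alone), at a median of 2.31 (camera adjusted p = 0.00108, and adjusted p = 0.44 with an estimated correlation). H2-Aa rose 7.15-fold, the invariant chain gene Cd74 6.06-fold and H2-Eb1 5.63-fold (adjusted p = 0.0300, and 0.222 without the mouse block or 0.127 with the slide as the block). In mouse 512 the medians were 1.25, 1.08, 0.55 and 1.28 for these 4 lists, against 3.17, 2.37, 2.66 and 2.40 in mouse 495 and 3.32, 3.33, 2.46 and 3.12 in mouse 485. No member passed (0) with mouse 495 or mouse 485 left out, and without mouse 512, 18, 9, 18 and 7 rose. With no filter 7, 5, 5 and 4 rose.

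Markers of glomerular and vascular cells had smaller medians than the immune cell marker lists in the main fit. With normexp the endothelial median of 0.66 lay above that of neutrophil markers (0.60). Of 15 endothelial markers, 8 rose and 0 fell (10 adjusted over the list alone), at a median of 0.84 (camera adjusted p = 0.000313, and adjusted p = 0.44 with an estimated correlation). The cadherin gene Cdh5 rose 2.47-fold, Plvap 2.16-fold and Eng 2.06-fold, and 1 member of the list passed with centring on the spike-in spots and 2 with no filter. Of 12 podocyte markers, 5 rose and 0 fell (5 adjusted over the list alone), at a median of 0.46 (camera adjusted p = 0.0269, and adjusted p = 0.44 with an estimated correlation). Among them were Wt1 (3.74-fold), Synpo (2.67-fold, with a second probe at -0.50), Ptpro (2.51-fold) and Plce1 (1.19 ± 0.20), the last named after its value was seen; the list lost its call without mouse 512 (camera adjusted p = 0.105), in the unpaired fit without its contralateral kidney (0.138) and on the spike-in scale (0.0501). Markers of tissue next to the kidney and of red cells did not pass as lists, except urothelial and smooth muscle markers with no filter on dim probes (median 0.87 over 10 members, camera adjusted p = 0.0253). Urothelial and smooth muscle markers had 0 of 6 members past the test (0 adjusted over the list alone; median 0.40, camera adjusted p = 0.28), with Actg2 at 0.52 ± 0.15. Of 4 adrenal and fat markers, the fatty acid binding protein gene Fabp4 alone rose, 2.88-fold (1 adjusted over the list alone; median -0.53, camera adjusted p = 0.974, and fry pointing upward with an adjusted p = 0.149). Of 4 red cell markers, 0 passed (0 adjusted over the list alone; median 0.23, which turned negative with quantile normalization, normexp and centring on the median, and mean -0.31, camera adjusted p = 0.974), with Slc4a1 at -2.05 ± 0.68. In mice 495, 485 and 512 the medians were 0.58, 0.72 and 1.04 for endothelium and 0.38, 0.45 and 0.79 for podocytes. Without mouse 495 or mouse 485, 0 members passed, and without mouse 512, 8 and 5 rose and 1 podocyte marker fell.

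The genes fixed in advance show how the pairs behaved. Fibronectin (Fn1) rose 6.51-fold (2.70 ± 0.47, adjusted p = 0.0316) and Tgfb1, the fibrogenic cytokine, 4.62-fold (2.21 ± 0.36, adjusted p = 0.0296). Acta2, smooth muscle actin and a marker of myofibroblasts, did not pass (0.30 ± 0.15, adjusted p = 0.174); its 4 probes ranged from 0.18 to 1.13, and it was called with quantile normalization (0.75, adjusted p = 0.0414) and lay at -0.00 with centring on the median. Lcn2, the injury marker NGAL, stood at 3.94 ± 1.5 (adjusted p = 0.11), with 5.22 in mouse 495, 6.81 in mouse 485 and -0.22 in mouse 512. Havcr1, the injury marker KIM-1, stood at -0.39 ± 0.96 (adjusted p = 0.76), with 0.91, 1.02 and -3.10 in these mice and 2.06 from a second probe. The phosphate transporter gene Slc34a1 was at -2.57 ± 0.70 (adjusted p = 0.0589), with -3.98, -3.04 and -0.68. Uromodulin (Umod) was at -0.17 ± 0.35 (adjusted p = 0.711), with -0.71, -0.57 and 0.75, and turned positive with quantile normalization (0.24), centring on the spike-in spots (0.15), without mouse 495 (0.09) and without mouse 485 (0.02). Without mouse 512, Lcn2 (6.02, adjusted p = 0.00385), Slc34a1 (-3.51, adjusted p = 0.0043), Umod (-0.64, adjusted p = 0.0308) and Havcr1 (0.96, adjusted p = 0.012) all passed. Slc34a1 also passed with centring on the median (0.0364), the slide as the block (0.0372), an intensity trend (0.0486), the deposited value table (0.0366) and the spike-in scale (0.0176), and Lcn2 on the spike-in scale (0.0445). With mouse 495 or mouse 485 left out, Fn1 (adjusted p = 0.142 and 0.163) and Tgfb1 (0.136 and 0.165) did not.

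**Figure D3:**
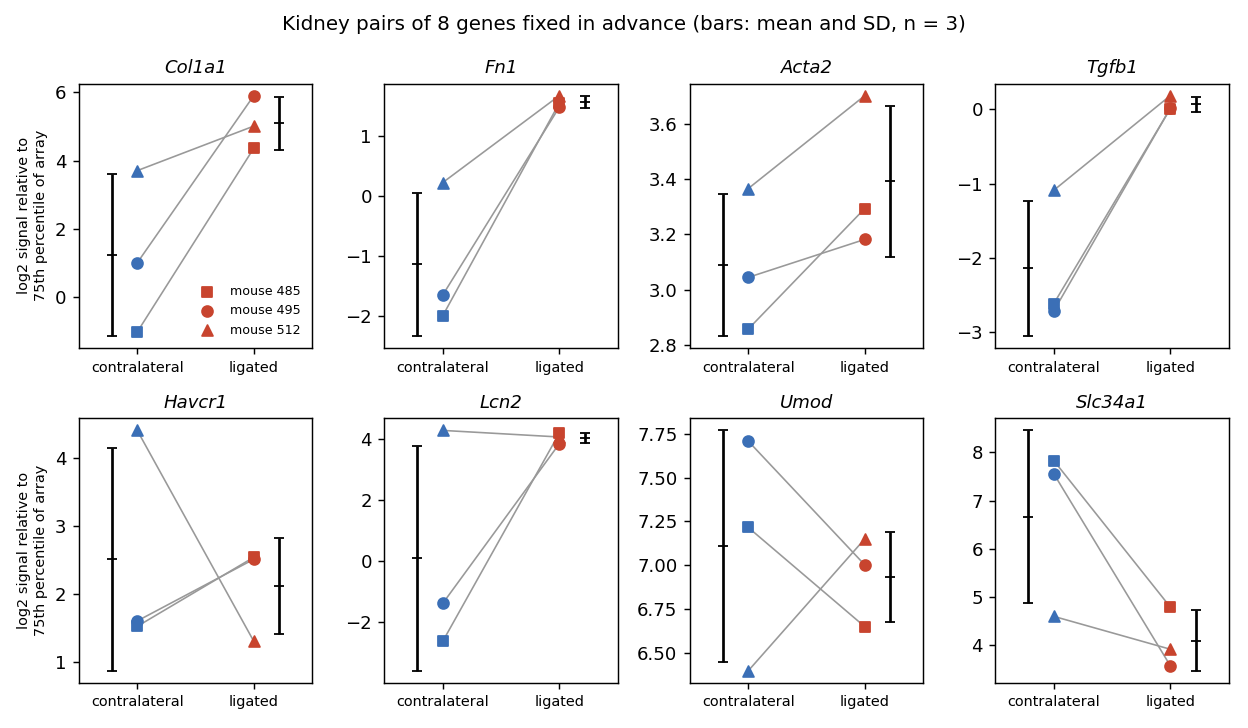
Log2 signal relative to the array's 75th percentile (y axis) of 8 genes in the contralateral and ligated kidney (x axis); each symbol is one mouse, lines join its kidneys, and bars give the mean and SD of 3 mice per group. Lcn2 lies at 4.27 in the contralateral and 4.05 in the ligated kidney of mouse 512, while the other 2 contralateral kidneys lie at -1.39 and -2.63.

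Over all lists, 27 of 33 passed camera at the preset correlation, 19 higher and 8 lower. With an estimated correlation 0 passed (adjusted p from 0.44 to 0.976, 2 lists at an unadjusted p under 0.05, the collecting duct and antioxidant lists). That variant had little power at 2 residual degrees of freedom. With fry 5 passed (23 at an unadjusted p under 0.05): collecting duct (adjusted p = 0.0068), podocyte (0.0216), NADPH oxidase (0.0216), antioxidant (0.0216) and T and NK cell lists (0.0423).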

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

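The spike-in scale, the unpaired fit without the contralateral kidney of mouse 512 and the gene families were chosen after seeing the data. Against 6019 genes and 4320 at least 2-fold, limma called 2662 and 2621 with no filter on dim probes, 3102 with centring on the spike-in spots (each at least 2-fold) and 11185 and 7084 in the unpaired fit without the contralateral kidney of mouse 512. Leaving out 1 mouse gave 0 to 11122 genes, 0 to 7271 at least 2-fold and 26 to 27 lists; the 0 came without mouse 495 or mouse 485 (4979 and 5019 genes at an unadjusted p under 0.05) and the highest counts without mouse 512, a fit that shares 5975 calls with the paired one. With no filter, 28468 genes share the adjustment; for the other settings the cause was not tested. Without the replicate block 5538 genes passed, with quantile normalization 5470 and with normexp 4779. The balance of the calls was 2561 higher and 5938 lower with centring on the median, 2554 and 5926 in the deposited value table, 1992 and 2787 with normexp, 1760 and 902 with no filter, and 2449 and 653 with the spike-in spots. Camera with an estimated correlation passed 0 of 33 lists (2 at an unadjusted p under 0.05) and fry 5 (23 unadjusted), while 25 to 29 passed camera at its preset correlation under the other settings. Of the 112 named genes, 104 lost their call without mouse 495 and 104 without mouse 485, 28 with no filter, 11 without the block, 11 on the spike-in scale, 7 with normexp, 4 with quantile normalization and 3 with the mean of the probes. Havcr1 ranged from -1.0983 (without mouse 485) to 0.9628 (without mouse 512), where it was called in the opposite direction. The sign followed mouse 512, whose difference was -3.10 against 0.91 in mouse 495 and 1.02 in mouse 485. Why mouse 512 differed was not tested. The median spot lay 2.70 times over its background on the dimmest array, and changes of genes near background (the 365 rises with no contralateral array above it) are limited by that.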

Other observations

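The gene families below, the tests of a slide difference and of a wrong label, and the test of a lower tubule share were chosen after the results were seen. Families of transport and detoxification fell. They overlap with the fixed lists and are not independent of them. The solute carriers include proximal tubule markers such as Slc22a6 and Slc22a8, and the vacuolar ATPase family includes collecting duct markers. Psmb8 and Psmb9 of the proteasome family stand in the interferon response list. Of 308 solute carrier genes, 112 fell and 29 rose (median log2 fold change -0.73, camera adjusted p = 9.97e-06, and adjusted p = 0.333 with an estimated correlation). Of 11 UDP-glycosyltransferases (Ugt), 8 fell and 0 rose (median -1.79), led by Ugt3a1 (-3.23 ± 0.65), Ugt3a2 (-3.22 ± 0.54) and Ugt1a9 (-3.05 ± 0.28). Of 10 carboxylesterases, 4 fell (median -3.03), namely Ces2f (-3.44), Ces2c (-3.07), Ces2b (-3.00) and Ces2e (-1.63). Of 54 cytochrome P450 genes 12 fell, while Cyp1b1 (2.37), Cyp2c65 (2.24), Cyp4v3 (1.36) and Cyp4f18 (0.75) rose. Of 22 subunits of the vacuolar ATPase, the proton pump of intercalated cells and lysosomes, 15 fell and 0 rose (median -0.93, camera adjusted p = 3.10e-06, and adjusted p = 0.333 with an estimated correlation), with Atp6v1c2 at -1.91 ± 0.25 and Atp6v0a4 at -1.78 ± 0.22. Of 39 proteasome subunits 20 fell (median -0.66), and the 3 that rose were the subunits of the immunoproteasome: Psmb8 (2.63 ± 0.38), Psmb9 (2.24 ± 0.29) and Psmb10 (1.77 ± 0.40). The medians of these families stayed negative under quantile normalization, centring on the median, normexp and the spike-in scale, but changed in size. That of the proteasome was -0.20 with quantile normalization, -0.34 on the spike-in scale and -0.97 with centring on the median. For solute carriers it was -0.41 on the spike-in scale and -1.04 with centring on the median. The median of 89 ribosomal protein genes (-0.05) became 0.45 with quantile normalization and 0.27 on the spike-in scale. Of these genes Rps27l alone fell (-0.83 ± 0.15). Differences within the pair were smaller in mouse 512, whose contralateral kidney lay toward the ligated ones. The medians in mice 495, 485 and 512 were -4.28, -3.18 and -0.78 for carboxylesterases and -1.38, -1.10 and -0.23 for cytochrome P450 genes. They were -1.70, -1.82 and -1.18 for UDP-glycosyltransferases and -0.88, -0.86 and -0.38 for solute carriers. For the vacuolar ATPase they were -1.01, -1.11 and -0.72, and for the proteasome -0.64, -0.87 and -0.46. With mouse 495 or mouse 485 left out, 0 genes of any family passed in limma, and with an estimated correlation no family passed (adjusted p from 0.319 to 0.882).

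Families of immune receptors rose. Of 27 C-type lectins, 18 rose and 1 fell (median 2.49, camera adjusted p = 6.35e-06, and adjusted p = 0.319 with an estimated correlation), among them Cd209d (4.13 ± 0.41) and the beta-glucan receptor gene Clec7a (3.79 ± 0.52), while Clec2h fell (-2.64 ± 0.40). Of 6 Fc receptor genes, 5 rose: Fcgr3 (3.36), Fcgr1 (3.15), Fcer1g (2.70), Fcgr4 (2.24) and Fcer2a (1.63). Fcgr3 and Fcgr1 are also in the macrophage list and Fcer2a in the B and plasma cell list. All 4 eosinophil-associated ribonucleases rose (median 4.85). Of 31 serpins, 15 rose, with Serpina3g at 3.52 ± 0.57, and Serpinf2 (-2.44), Serpina3b (-2.38) and Serpina3a (-1.66) fell. Of 32 protocadherins, 21 rose and 2 fell, Pcdh17 (-1.47) and Pcdh7 (-0.69). Protocadherins, ribonucleases and the Ugt and Ces families hold near-identical members whose probes may share signal, and with normexp the median of the protocadherins was 0.43 against 1.63, that of the lectins 0.57 against 2.49, and that of the ribonucleases 2.43 against 4.85. Mouse 512 had the smallest median in each of these families, with 1.44, 1.80 and 0.47 in mice 495, 485 and 512 for serpins, 2.70, 2.28 and 1.45 for lectins, 1.79, 1.75 and 1.06 for protocadherins, 2.60, 2.56 and 1.84 for Fc receptors and 5.14, 5.31 and 4.09 for the ribonucleases. These calls too were lost (0 genes) with mouse 495 or mouse 485 left out.

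The contralateral kidney of mouse 512 lay at 0.638 on the axis from the other contralateral (0) to the other ligated kidneys (1). Against the mean of the other 2 contralateral kidneys it held 77.9-fold more Lcn2, 7.19-fold more Havcr1, 15.6-fold more Top2a and 13.1-fold more Col1a1. Above both lay 22 of 22 cell cycle genes, 16 of 17 macrophage markers (median log2 difference 1.97) and 7 of 7 MHC class II genes (2.00). Below both lay 20 of 21 proximal tubule markers (-2.03). T and NK cell markers (0.28), endothelial markers (0.01) and neutrophil markers (-0.29) lay near the other contralateral kidneys. For endothelial markers this says little, since the other ligated kidneys lay only 0.60 away. A slide difference is argued against, since the ligated kidney on the same slide was displaced by 0.081, and so is a linear mix of both kinds of RNA: the ligated-type fraction was 0.312 (quartiles 0.194 and 0.535) from 670 genes higher and 0.953 (0.881 and 0.992) from 196 genes lower at least 8-fold in the other mice, a difference of 0.641. A ligated kidney of this experiment under the wrong label is argued against by the genes higher in ligated kidneys alone. Those 670 genes lay at a median of 0.602 (quartiles 0.467 and 0.781) of the log2 distance, against 1.044 (0.954 and 1.134) in the ligated kidney of mouse 512. The log2 signals of Retnla (-5.47), Ear1 (-4.74) and Cd3g (-4.82) were near the other contralateral kidneys, but those of Spp1 (8.32) and Mki67 (1.98) were near the ligated ones. The 196 lower genes lay nearer the ligated kidneys, at a median of 0.834 (quartiles 0.67 and 0.965). This array also correlated more with the ligated kidneys of mice 495 and 485 (0.9702 and 0.972) than with their contralateral kidneys (0.9554 and 0.9465). A sample from outside these pairs and a kidney that was itself altered stay open, and no biological explanation was tested.

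Respiratory chain genes were lower in each mouse, and the scaling to the 75th percentile was weighed because that percentile rose in the ligated kidneys of mice 495 and 485. On the spike-in scale, which does not use it, the medians were -1.1683, -1.0861 and -1.1041 in mice 495, 485 and 512, which argues against that scaling as the whole cause. A smaller share of tubule cells and a fall within those cells may each contribute and were not separated.

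Immune cell markers rose by unequal amounts. A lower share of tubule cells alone would raise the markers of every other cell type alike, but the macrophage median exceeded that of endothelial markers by 2.3103, more than the widest quartile range of the lists compared (1.16), which argues against it as the whole cause for macrophage markers. More macrophages and higher expression per cell may both contribute and were not separated. For B and plasma cell and neutrophil markers a lower tubule share stays possible. Their differences from endothelial markers (0.7779 and 1.1078) and from podocyte markers (1.1646 and 1.4945) lay within the widest range of these lists (1.6582). T and NK cell markers exceeded endothelial markers by 1.6652, barely over that range, and podocyte markers by 2.0519. That list was not settled, since its lead over endothelial markers barely passed the range. With normexp these T and NK cell differences were 0.2084 and 0.59. The T and NK cell, B and plasma cell and neutrophil medians were then 0.87, 0.86 and 0.60, close to the endothelial 0.66. The offset added in normexp shrinks log2 changes of dim probes more than those of bright ones. Of 15 endothelial markers 15 were above background on every contralateral array, against 11 of 13, 7 of 10 and 3 of 8 in these lists. The normexp medians therefore cannot show whether a lower tubule share explains them.

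Other splits of the arrays were fitted too. Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave as many as 6019 genes, 1 as many as 4320 genes at least 2-fold and 1 as many as 27 lists; the highest others were 0, 0 and 26. Among the other splits that part all 3 pairs, limma called 0 genes and camera 21, 14 and 15 lists. With 10 splits the share cannot fall under 0.05. The splits that do not part all 3 pairs part only 1, so with the mouse block their effect rests on 1 mouse. The others reverse the direction of 1 mouse, so a gene that changed alike in all 3 mice cannot pass there. The 0 genes of the other splits were therefore likely from the design and are no separate evidence.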
